A study of Rattus norvegicus with 12 samples.

How the data were processed

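Total RNA of rat exosomes and of rat cells was measured on 12 Illumina expression arrays of 1 chip after biotin labelling of cRNA, per the labels' protocols. The groups were taken from the labels: 3 arrays of exosomes from ASML cells (wt exosomes), 3 arrays of exosomes from ASML cells with a CD44v knockdown (kd exosomes), and 2 arrays each of B12 cells left untreated, treated for 24 h with wt exosomes and treated for 24 h with kd exosomes.

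The deposited non-normalized table holds, per the file headers, a mean intensity and a p-value for each probe and array, and the software that made them is not given in the sources used here. The deposited p-value was near 1 at each array's background signal and small on both sides of it, so it was read as a two-sided p-value against background. It was converted to a one-sided detection p for the background correction only. A probe counted as detected on an array when the deposited two-sided p-value was under 0.05 and its intensity lay above background. The background level was taken from probes with a deposited p-value above 0.9. Of 23365 rows, 848 had no identifier, and 280 identifiers stood on 571 rows; these were left out, which left 21946 probes. The platform table named 1 gene symbol for 13129 of them, several symbols for 0 and none for 8817. The gene IDs of 13088 probes were found in the GRCr8 gene table, which was used for symbols only and changed 0 of them. The deposited value table holds intensities on a linear scale, not centred, which the authors had normalized by a method not stated. Their rank correlation with the same array's non-normalized intensity was 0.991 to 0.9999. The medians of its columns were 145, 134 and 138 for the wt exosomes, 125, 127 and 145 for the kd exosomes, 121 and 120 for untreated B12 cells, 120.5 and 121 for B12 cells with wt exosomes and 121.5 and 121.2 for B12 cells with kd exosomes. It was used as an alternative only.

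Intensities were background-corrected by a normal-exponential model with an offset of 16, quantile normalized and taken as log2 (neqc of limma 3.58.1 in R 4.3.3), separately for the 6 exosome arrays and the 6 B12 arrays. Probes detected on all arrays of at least 1 group were kept. Each probe was tested with limma (lmFit, and eBayes with a trend of the spread on the mean), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 3 B12 groups shared 1 estimate of the spread, with 3 residual degrees of freedom, and the exosome fit had 4. A probe detected on no array of a group has only a bound there: the mean log2 signal of the other group over all its arrays was set against the mean, over the dim group's arrays, of the higher of the probe's own signal and the lowest detected signal. The changes in log2 printed for such probes are fitted values, not bounds. A gene with several probes was given by the probe with the highest mean. Every gene named in the planned comparisons had a single probe in the fit.

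Gene lists, 22 in number, were fixed from knowledge of the tissues and of exosomes, and those with at least 5 measured genes were tested with limma's camera at an inter-gene correlation of 0.01, adjusted over the lists. Each call was set beside camera with an estimated correlation and beside fry. Genes named in the text were chosen by a rule: the 10 with the largest change in each direction among probes past the threshold whose groups do not overlap, filled up by the smallest unadjusted p among probes with groups that do not overlap where fewer passed; up to 4 measured members of each list with the smallest p; and always Cd44 and Tspan8. Genes that fill up the rule are given as values, not as changes. Provisional symbols and probes without a single symbol were skipped. Genes named in the closing observations were chosen after their values were seen. A set of 200 genes that marks each exosome type was taken by rank difference over the B12 cells treated with the other exosomes, and its median change was also set against 10000 random lists matched on mean expression.

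The groups share replicate numbers, and the labels do not say what a number marks. In the B12 cells, deviations from the group means correlated at 0.773 to 0.799 between arrays with the same number. With 2 arrays per group the deviations mirror each other, so the pairs of number 2 repeat those of number 1. The first principal component, with 74.3% of the variance, separated number 1 from number 2. The numbers were therefore read as pairing the B12 arrays, on the evidence of the data and not of the labels, and a fit with the replicate number as a block is given wherever it changed a call or moved a count by over 1.5 times. In the exosomes the numbers did not pair the arrays.

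The gene tests were tested on simulated data made from the real means and spreads in 20 simulations per comparison. In the exosome comparison, changes of 1 and 2 in log2 were recovered in 24.4% and 87.1% of cases, with 6.85 false calls on average over 8699 probes. For B12 cells with wt exosomes against untreated cells, 0% and 9.4% were recovered without the block and 41.1% and 98% with it, with 0.85 and 15.15 false calls on average over 11631 probes. A shifted list, that of the cell cycle genes, was recovered in 20 of 20 simulations of each. Genes were drawn independently there, while the estimated correlation of that list was 0.378 in the B12 data. This recovery therefore says nothing on lists whose genes vary together. The share of probes detected per array was 42.8% to 54.3%, and the number of arrays limits the precision.

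The alternatives tried were no background correction, a normal-exponential correction with an offset of 50, all 12 arrays normalized together, median scaling, the authors' values, no filter, detection at p under 0.01 on all arrays, all 12 arrays in 1 fit, no trend of the spread, array weights, the replicate block, and each array left out in turn. Rows without an identifier as negative controls, cyclic loess, the exosome comparison without kd replicate 3 under each other scaling, and the block together with an estimated correlation or fry were added after the data were seen. The comparisons, tests, lists and other alternatives were fixed before the data were examined, except that the plan took the detection p-values as one-sided.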

Results

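The arrays measured messenger RNA in exosomes shed by ASML cells, a metastasizing rat pancreatic adenocarcinoma line, and in B12 cells, a rat line of lymph node stroma that such exosomes can reach. The exosomes came from wild-type ASML cells (3 arrays) or from ASML cells with a knockdown of the CD44 variant isoforms (CD44v), adhesion molecules of metastasizing tumour cells (3 arrays). B12 cells were untreated, treated for 24 h with wt exosomes or treated for 24 h with kd exosomes (2 arrays each). Exosome arrays were dimmer than cell arrays. The mean signal over background was 108, 173 and 138 on the wt exosome arrays, 299, 244 and 100.1 on the kd exosome arrays, and 505 to 588 on the B12 arrays. Of 21946 probes, 42.8%, 46.3% and 45.8% were detected on the wt exosome arrays, 52.2%, 47% and 42.8% on the kd exosome arrays, and 53.2% to 54.3% on the B12 arrays.

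Cd44, the targeted gene, was detected on all 12 arrays. Its signal over background was 61.9, 103 and 59.3 in wt exosomes and 57.8, 44.5 and 17.3 in kd exosomes. As a share of the array's mean signal over background this was 57.1%, 59.6% and 42.9% in wt exosomes and 19.4%, 18.2% and 17.3% in kd exosomes. After normalization, Cd44 averaged 6.80 ± 0.22 in wt and 5.52 ± 0.17 in kd exosomes (log2, SD, n = 3 each). The difference was −1.29 ± 0.25 (SE), and the kd arrays 1, 2 and 3 lay at −1.26, −1.13 and −1.47 from the wt mean. It did not pass limma's adjusted threshold (adjusted p = 0.383). Without kd replicate 3 it passed (−1.28, adjusted p = 0.00206), though not under median scaling (−0.50, adjusted p = 0.227). With all arrays it passed with array weights (−1.15, adjusted p = 8.75e-04), and it lay between −1.62 and −0.61 over the scalings. Kd replicate 3 was left out for its values. Array weights are also estimated from the values, and give less weight to an array that strays from its group. The p values with these choices therefore do not hold as tests of the knockdown. The position of the probe relative to the variant exons is not given in the sources used here, so it may not check the knockdown itself.

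Exosomes of knockdown and wild-type cells were compared to ask whether loss of CD44v changes the RNA that ASML cells export. The lowest values in kd exosomes among the genes with the smallest p, after Cd44, included Vim, the intermediate filament of mesenchymal cells (−1.04 ± 0.19 SE; kd arrays at −1.13, −1.30 and −0.69 from the wt mean), Fdps, an enzyme of cholesterol synthesis (−0.98 ± 0.18) and Ramp1, a receptor-modifying protein (−1.26 ± 0.27). The highest included Gpx8, a peroxidase of the endoplasmic reticulum (1.22 ± 0.28), Cimap1c (1.12 ± 0.23) and Fam222b (1.11 ± 0.24). The kinase Lck and the chemokine Ccl5 were not detected in wt exosomes, and stood at least 2.15-fold and 2.02-fold higher in kd exosomes under the scaling used here. Tspan8, a tetraspanin of tumour exosomes, lay at 8.47 ± 0.68 in kd and 9.29 ± 0.13 in wt exosomes (log2, SD, n = 3 each), with the kd arrays at −1.18, −1.24 and −0.03 from the wt mean. Without background correction the fitted differences of Lck, Ccl5, Cimap1c, Fam222b and Ramp1 were 0.46, 0.31, 0.39, 0.60 and −0.42, against 1.38 and 1.04 for Lck and Ccl5 here. Under median scaling Vim, Fdps and Tspan8 lay at −0.32, −0.26 and −0.08, and Gpx8 and Fam222b at 1.98 and 1.72. With array weights each of these genes passed (adjusted p at most 0.001025, that of Ramp1), which, as for Cd44, is no test of the knockdown. Limma called 0 of 8699 probes (5926 genes) with all 6 arrays. The lowest adjusted p was 0.383, and 1127 probes had an unadjusted p under 0.05 (444 higher, 683 lower) where chance gives 435. Other groupings of the 6 arrays, 3 against 3, that kept kd replicates 1 and 2 together gave 1285, 1507 and 3414. Groupings that parted these 2 arrays gave 94 to 227. The excess over chance therefore follows these 2 arrays and cannot be assigned to the knockdown. The kd and wt groups did not overlap for 1558 probes, or 17.9%, where chance gives 10%. That 10% takes the 6 arrays as interchangeable. As kd replicates 1 and 2 lie close together, this excess cannot be assigned to the knockdown either. Under median scaling the median change of all probes was 0.36, against −0.036 under the scaling used here. It turned that split to 360 higher and 260 lower (58.1% against 39.4% higher), and under it Krt7 and Spint2 turned from −0.59 and −0.64 to 0.01 and 0.11, which still lies below that median of all probes. The count at an unadjusted p under 0.05 fell to 457, 650 and 613 without wt replicates 1, 2 and 3, to 413 and 381 without kd replicates 1 and 2, and rose to 5279 without kd replicate 3. Array weights called 4146 probes with all 6 arrays (4796 at an unadjusted p under 0.05), and all 12 arrays in 1 fit called 1.

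**Figure D1:**
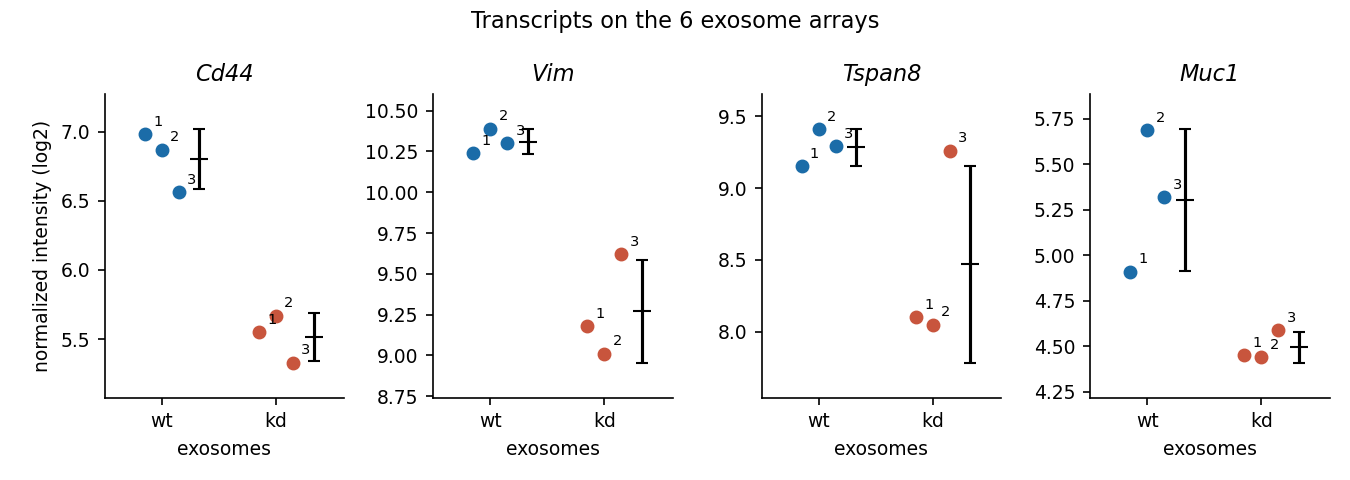
Normalized intensity (log2) of Cd44, Vim, Tspan8 and Muc1 on each of the 3 wt and 3 kd exosome arrays, with the group mean and SD. Cd44 lies at 6.80 in wt and 5.52 in kd exosomes on average, and for Tspan8 kd replicate 3 lies among the wt arrays.

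Epithelial carcinoma markers were lower in kd exosomes, with a median of −0.54 and 19 of 21 genes lower, the only one of 20 tested lists past the threshold. Camera gave it an adjusted p of 2.02e-04, but adjusted p = 0.558 with an estimated correlation, and fry gave an adjusted p of 0.171. Among these markers, the mucin Muc1 was not detected in kd exosomes and stood at least 1.74-fold higher in wt exosomes, and Krt7, Spint2 and the tight junction gene Cldn1 lay at −0.59 ± 0.21, −0.64 ± 0.24 and −0.56 ± 0.21 (SE). Without background correction Muc1 and Cldn1 lay at −0.23 and −0.15, against −0.81 for Muc1 here. With array weights Muc1, Krt7, Spint2 and Cldn1 passed (adjusted p at most 0.0174, that of Cldn1), again no test of the knockdown. The list's median was −0.64 and −0.70 for kd replicates 1 and 2 and −0.12 for kd replicate 3. The number of its genes past the threshold adjusted over the list alone was 0 in limma, with 7 lower at an unadjusted p under 0.05. Under median scaling the list's median turned to 0.07, below the median of all probes of 0.36, and it was −0.23 without background correction, −0.29 with an offset of 50, −0.34 in the authors' values and −0.35 with no filter. The number of lists past the threshold was 3 under median scaling, 3 with detection on all arrays, 2 under cyclic loess, 2 without wt replicate 2, 2 without kd replicate 2 and 5 without kd replicate 3.

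Kd replicate 3 stood apart from the other kd exosome arrays. Across all probes, kd replicates 1 and 2 correlated at 0.987 with each other and at 0.848 and 0.834 with kd replicate 3, which correlated at 0.949 to 0.971 with the wt exosome arrays. On the first principal component (75.9% of the variance) kd replicates 1 and 2 lay at 52.9 and 57.1, kd replicate 3 at −41.4 and the wt arrays at −28.2, −11.3 and −29.2. These are correlations across probes, which are not independent replicates. Kd replicates 1 and 2 were also the brightest exosome arrays and kd replicate 3 the dimmest, so signal strength and this grouping run together.

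**Figure D2:**
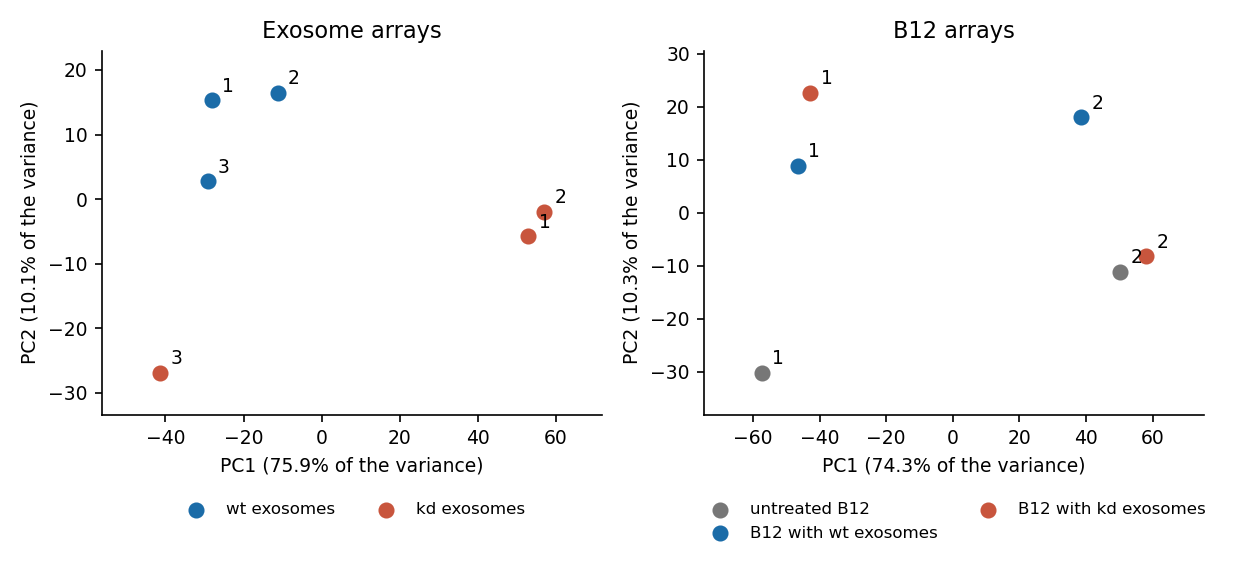
First and second principal components of the 6 exosome arrays and of the 6 B12 arrays, with the share of variance on each axis; points are arrays, labelled by group and replicate number. Kd exosome replicate 3 lies at −41.4 with the wt exosome arrays, and B12 arrays separate by replicate number.

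Kd replicates 1 and 2 were therefore also compared alone with the 3 wt exosome arrays, a choice that follows from the place of kd replicate 3. As that array was left out for its values, the adjusted p values below do not hold as tests of the knockdown, and the calls only describe how these 2 arrays stood apart. Gja1, the gap junction protein connexin 43, was at least 22.9-fold higher in these kd exosomes (limma adjusted p = 1.99e-06). The intracellular channel gene Clic2 lay higher by 4.31 ± 0.18 (log2, SE, n = 2 against 3; adjusted p = 7.73e-07) and Aldh1a1, a retinal dehydrogenase, by 4.14 ± 0.25 (adjusted p = 6.51e-06). Interferon and antigen presentation genes went both ways, with 12 called higher and 9 called lower. Those higher included Mx2 by 4.13 ± 0.41, Irf7 by 2.94 ± 0.23 and Gbp2 by 2.56 ± 0.26. Ifih1, a sensor of double-stranded RNA, was at least 4.93-fold higher. The replication genes Mcm6 and Mcm2 lay higher by 1.37 ± 0.11 and 1.34 ± 0.13. Vdac2, a channel of the mitochondrial outer membrane, was at least 39.2-fold lower (adjusted p = 1.5e-07), Slpi, an inhibitor of leukocyte proteases, at least 28.9-fold, and the matrix protein Sparc at least 7.5-fold. These bounds belong to the scaling used here: without background correction the fitted differences of Gja1, Ifih1, Vdac2, Slpi and Sparc were 2.63, 1.04, −3.21, −2.92 and −1.555, against 4.775, 2.54, −5.46, −5.10 and −3.23 here. Tgm1 lay at −3.74 ± 0.12, Akr1b8 by −3.35 ± 0.12, Col1a2 by −3.71 ± 0.52 and the platelet chemokine Pf4 by −3.62 ± 0.23. The neutrophil chemokines Cxcl6 and Cxcl1 lay at −2.87 ± 0.24 and −2.05 ± 0.33, and Cxcl10 at 1.76 ± 0.19. Over the scalings the values nearest to 0 were 2.735 for Clic2, 2.72 for Mx2, −2.11 for Col1a2, −2.305 for Pf4, −2.135 for Akr1b8, −1.81 for Cxcl6, −0.78 for Cxcl1 and 1.12 for Cxcl10, and Mcm6, Mcm2 and Cxcl10 reached 2.53, 2.685 and 2.95. Limma called 4304 of 10170 probes, 2572 higher and 1732 lower.

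These calls depend on which arrays and which scaling are used. With kd replicate 3 the number of called probes was 0 (4146 with array weights), and the direction on that array matched in 1652 of the 4304 calls, or 38.4%. On kd replicate 3, Mx2 lay at −1.32 from the wt mean, and Pf4 and Hba-a1, a globin gene, lay above it at 1.04 and 3.61, where Hba-a1 was at least 15.9-fold lower in kd replicates 1 and 2 (adjusted p = 0.00954). Without background correction the fitted difference of Hba-a1 was −2.21 (adjusted p = 0.0514), against −4.04 here. Over 7 scalings the number of calls was 4212 to 5811, and 2439 probes were called in 1 direction under all of them. Under median scaling the median change of all probes was 0.73, against 0.07 under the scaling used here, with 5324 higher and 487 lower (91.6% against 59.8% higher). Under it, Tspan8, Vim and Fdps turned from −1.21, −1.21 and −1.11 to 0.14, 0.12 and 0.20, which lies below that median of all probes. Cxcl1 did not stay past the threshold under median scaling.

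In the same comparison of kd replicates 1 and 2, 5 of 21 tested lists passed camera, all lower. Epithelial carcinoma markers had a median of −0.70 (adjusted p = 1.55e-04; adjusted p = 0.484 with an estimated correlation), with Esrp1, a splicing factor that shapes CD44 isoforms, at −1.49 ± 0.12 and the protease Prss8 at −1.72 ± 0.18 (SE). Chemokines and cytokines had a median of −0.53 (adjusted p = 0.0156; adjusted p = 0.638 with an estimated correlation). Stroma and fibroblast markers had a median of −0.32 (adjusted p = 0.0156; adjusted p = 0.618 with an estimated correlation), with Pdpn at least 2.57-fold lower under the scaling used here (fitted −1.61, and −0.58 without background correction). Oxidative stress genes had a median of −0.25 (adjusted p = 0.0201; adjusted p = 0.484 with an estimated correlation), with Akr1b8 at −3.35 ± 0.12, Mgst1 at −1.85 ± 0.13 and the metallothionein Mt1 at −1.60 ± 0.09. Cytosolic ribosomal proteins had a median of −0.13 (adjusted p = 0.015; adjusted p = 0.618 with an estimated correlation), with Rps24 at −1.82 ± 0.14 and Rps13 at −1.57 ± 0.10. Adjusted over the list alone, the counts lower were 13, 10, 5, 16 and 21 in that order, and the counts higher 2, 2, 0, 8 and 9. Over the scalings the medians of the epithelial, stroma, oxidative stress and ribosomal lists turned to as much as 0.36, 0.04, 0.82 and 0.43, where the median of all probes reached 0.73, while the chemokine list stayed negative, up to −0.16. Under median scaling Esrp1, Prss8, Mgst1, Rps24 and Rps13 lay at −0.21, −0.54, −0.51, −0.59 and −0.31 and were not past the threshold, and Mt1 lay at −0.71. Fry passed the epithelial (adjusted p = 0.00541), oxidative stress (0.00842) and ribosomal (0.0275) lists, and not the chemokine (0.116) and stroma (0.0609) lists. It also passed cell cycle inhibitors and p53 targets (0.0311, toward lower; camera adjusted p = 0.367) and interferon and antigen presentation genes (0.00541), toward higher (median 0.40, with 16 of 28 higher; camera adjusted p = 0.616).

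B12 cells with wt exosomes were compared with untreated B12 cells to ask what ASML exosomes change in lymph node stroma. Cell cycle genes fell by 1.00 (median over 42 genes), and 39 were lower. Camera gave an adjusted p of 9.1e-34, but adjusted p = 0.752 with an estimated correlation, and fry gave 0.561. The mitotic spindle gene Aspm lay at −1.98 ± 0.30 (SE; −1.77 and −2.20 for replicate numbers 1 and 2), Nusap1 at −1.97 ± 0.35, Prc1, which cross-links the central spindle, at −1.76 ± 0.28, the cyclin Ccnb2 at −1.78 ± 0.32 and the mitotic kinase Plk1 at −1.46 ± 0.30 (n = 2 each). Aspm, Nusap1 and Plk1 lay at −0.98, −0.86 and −0.73 in the authors' values. The list's median was −0.73 for replicate number 1 and −1.39 for number 2, and it stayed between −1.02 and −0.52 over all scalings (−0.65 without background correction, −0.52 in the authors' values). Adjusted over the list alone, 14 genes were lower, and 25 with the replicate number as a block. Markers of cell types differed as well within replicate number 1, where epithelial markers had a median of −0.61 and stroma markers 0.76, against 0.21 and −0.36 in number 2. Neither of these lists passed (camera adjusted p = 0.490 and 0.406). With the block, 2 adhesion genes and 1 oxidative stress gene were higher adjusted over the list alone, and 0 without it.

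**Figure D3:**
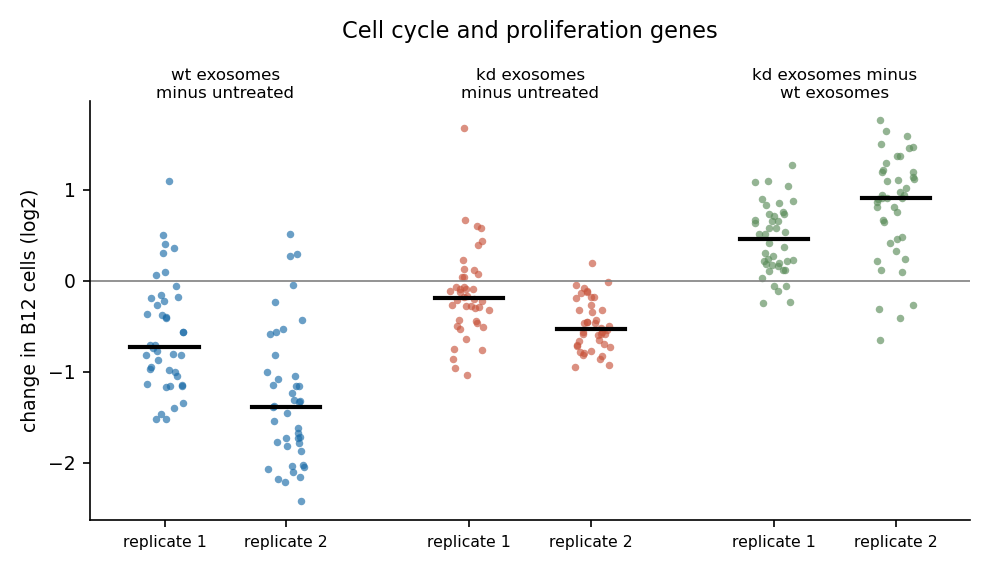
Change in log2 of each of the 42 measured cell cycle genes in B12 cells, by replicate number, for 3 comparisons; points are genes and bars are medians. With wt exosomes against untreated cells the medians are −0.73 and −1.39, and with kd against wt exosomes 0.46 and 0.91.

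Proteases and the unfolded protein response were the other lists past the threshold after wt exosomes, with adjusted p values of 0.0426 and 0.0244, and both had adjusted p = 0.826 with an estimated correlation, while fry passed 0 lists. Proteases and inhibitors had a median of 0.36, with 18 of 25 genes higher. Mmp3, a stromelysin, lay at 3.85 ± 1.43 (SE; 3.46 and 4.23 by replicate number), and Mmp10 was not detected in untreated cells and stood at least 4.63-fold higher, with 0.23 and 4.25 by replicate number. Unfolded protein and heat shock genes had a median of 0.16, with 18 of 28 higher, and included Creld2 at 1.02 ± 0.46, Dnajb11 at 0.58 ± 0.29, Dnajb9 at 0.52 ± 0.24 and the transcription factor Xbp1 at 0.46 ± 0.18. In the authors' values Mmp10, Creld2 and Dnajb9 lay at 0.81, 0.59 and 0.34, against 2.24 for Mmp10 here. Adjusted over the list alone, 0 genes of either passed in limma, with 1 gene of each at an unadjusted p under 0.05. The protease call was lost without untreated replicate 1 (0.738), wt replicate 2 (0.687) or kd replicate 1 (0.0718), and the unfolded protein call without untreated replicate 1 (0.271), wt replicate 1 (0.0664) or wt replicate 2 (0.609). The protease median was 0.58 without untreated replicate 2, 0.85 without wt replicate 1, 0.13 without untreated replicate 1 and 0.04 without wt replicate 2. The unfolded protein median was 0.28 without untreated replicate 2 and 0.25 without wt replicate 1. The protease call was also lost under median scaling (0.0538), in the authors' values (0.0528, median 0.11), under cyclic loess (0.0502), with all arrays normalized together (0.0568), with detection on all arrays (0.0588) and with array weights (0.0549). Its median was 0.15 without background correction, 0.193 with an offset of 50 and 0.19 with no filter. The unfolded protein call was also lost with no filter (0.0673, median 0.08) and with all 12 arrays in 1 fit (0.0542), and its median was 0.09 without background correction and in the authors' values and 0.10 with an offset of 50. Without untreated replicate 2, 6 lists passed.

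No single gene passed after wt exosomes. Outside these lists, the metallothionein Mt1 lay at 2.69 ± 0.81 (SE; 1.73 and 3.65 by replicate number), and the neutrophil chemokines Cxcl1 and Cxcl2 lay at 0.92 ± 0.25 and 3.66 ± 1.72. Most genes with the smallest p were near background: of the highest, most were not detected in untreated cells, among them Olr1, a receptor for oxidized lipoprotein (at least 3.38-fold), Asgr1 (at least 2.88-fold) and the kinase Tec (at least 1.89-fold), each with an adjusted p of 1. In the authors' values Olr1, Asgr1, Tec and Cxcl2 lay at 0.46, 0.38, 0.19 and 1.93, against 1.84, 1.52 and 1.00 for Olr1, Asgr1 and Tec here. Limma called 0 of 11631 probes (7908 genes), and 327 had an unadjusted p under 0.05 (124 higher, 203 lower) where chance gives 582. That count was 646 with the replicate block (272 higher, 374 lower; 0 called, lowest adjusted p = 0.533), 493 without untreated replicate 1, 589 without untreated replicate 2 and 525 without wt replicate 1. It was 707 with no filter, 134 with detection on all arrays and 178 with all 12 arrays in 1 fit. The groups did not overlap for 24.2% of probes, where chance gives 33.3% for arrays that are not paired. These arrays pair by number, so 33.3% is not the share to be met without a change. For the same reason 582 is not the count to be met in the fit without the block, whose spread includes the difference between numbers.

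B12 cells with kd exosomes were also compared with untreated cells, to ask whether exosomes of CD44v-deficient tumour cells act on the stroma. Camera passed 4 lists, each had adjusted p = 0.774 with an estimated correlation, and fry passed 0. Genes of the unfolded protein response were higher, with a median of 0.26 and 22 of 28 higher: the chaperone Hspa5 lay at 0.54 ± 0.27, Pdia3 at 0.51 ± 0.24 and Xbp1 at 0.39 ± 0.18 (SE, n = 2 each). Cholesterol and fatty acid synthesis genes were higher, with a median of 0.32 and 21 of 26 higher, with Acat2 at 0.93 ± 0.51, Cyp51 at 0.89 ± 0.47 and Dhcr7 at 0.72 ± 0.24. Cell cycle genes were lower, with a median of −0.37 and 37 of 42 lower, among them Ccnb2 at −0.73 ± 0.32 and Prc1 at −0.61 ± 0.28. Interferon and antigen presentation genes were lower, with a median of −0.16 and 21 of 27 lower, with Ifi35 at −0.54 ± 0.29, Ifih1 at −0.52 ± 0.26 and Igtp at −0.51 ± 0.32. Cyp51, Ifi35, Ifih1 and Igtp lay at 0.33, −0.34, −0.20 and −0.17 in the authors' values. The medians for replicate numbers 1 and 2 were 0.42 and 0.14, 0.51 and 0.15, −0.19 and −0.53, and −0.58 and 0.09 for these lists in that order, so the interferon list went opposite ways. The adjusted p values from camera were 2.71e-04, 0.00423, 5.16e-07 and 0.0148 in the same order. Adjusted over the list alone, 0 genes of each passed in limma, with 1 at an unadjusted p under 0.05, in the cholesterol list. Markers of cell types differed as well, mainly within replicate number 1. There epithelial markers had a median of −0.59 and stroma markers 0.88, against −0.12 and −0.03 in number 2. Neither of these lists passed without the block (camera adjusted p = 0.302 and 0.174).

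Single arrays decided most of these calls in the kd-treated cells. The cholesterol list fell to a median of 0.05 without kd replicate 2 (adjusted p = 0.916) and turned to −0.02 without untreated replicate 1 (0.719), and its median was 0.69 without untreated replicate 2 and 0.57 without kd replicate 1. The interferon call was lost without untreated replicate 1 (0.816), wt replicate 1 (0.093) or kd replicate 1 (0.683, median −0.04), and its median was −0.45 without untreated replicate 2 and −0.37 without kd replicate 2. It was also lost with no filter (0.196), and the median was −0.25 with detection on all arrays. The unfolded protein call was lost without kd replicate 1 (0.0716) or kd replicate 2 (0.0526), and the cell cycle call without untreated replicate 2 (0.0774). In the authors' values the unfolded protein median was 0.15 and the cell cycle median −0.20. Without kd replicate 2, 2 lists passed. With the replicate number as a block, 7 lists passed and not 4, and each of the 3 added had adjusted p = 0.766 with an estimated correlation. Epithelial carcinoma markers were lower (median −0.42; adjusted p = 0.00151 against 0.302 without the block), with the intestinal cadherin Cdh17 at −2.10 ± 0.33 and the transcription factor Ehf at −1.22 ± 0.27 (SE with the block) and 3 genes lower adjusted over the list alone. Proteases were higher (median 0.20; adjusted p = 0.0144 against 0.302), with Mmp16 at 1.10 ± 0.37 and the inhibitor Cst3 at 0.59 ± 0.16. NF-kappaB and immediate early genes were lower (median −0.07, mean −0.26; adjusted p = 0.00542 against 0.0741), with Klf4 at −1.29 ± 0.35. The block also gave calls adjusted over the list alone, where there were 0 without it: 1 adhesion gene higher and 1 lower, 1 oxidative stress gene higher and 1 lower, and 1 angiogenesis gene lower. Cdh17, Ehf and Mmp16 lay at −1.35, −0.35 and 0.56 in the authors' values. With an estimated correlation or with fry, 0 lists passed with or without the block.

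Single genes after kd exosomes did not pass either. Cxcl1 lay at 1.00 ± 0.25 (SE; 0.96 and 1.05 by replicate number), and Mt1 at 2.38 ± 0.81. Most genes with the smallest p were not detected in 1 of the groups, such as Or52ad1 (at least 2.03-fold lower) and Spata9 (at least 1.73-fold lower), each with an adjusted p of 1, and in the authors' values these lay at −0.27 and −0.32, against −1.17 each here. Limma called 0 of 11631 probes, and 285 had an unadjusted p under 0.05 (140 higher, 145 lower) where chance gives 582. That count was 668 with the replicate block (327 higher, 341 lower; 0 called, lowest adjusted p = 0.858), 624 without untreated replicate 2 and 437 without kd replicate 2. It was 643 with no filter, 79 with detection on all arrays and 126 with all 12 arrays in 1 fit. In the authors' values the split was 159 higher and 102 lower (60.9% against 49.1% higher). The groups did not overlap for 22.1% of probes, where chance gives 33.3% for arrays that are not paired, unlike these. Without the block, 582 also holds only for arrays that are not paired.

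Both treated groups were compared directly, to ask whether CD44v in the tumour cell changes what its exosomes do. Camera passed 3 lists, each had adjusted p = 0.641 with an estimated correlation, and fry passed 0. Cell cycle genes were higher with kd than with wt exosomes: the median was 0.67, and 38 of 42 genes were higher. Aspm lay at 1.34 ± 0.30, Nusap1 at 1.26 ± 0.35, Prc1 at 1.16 ± 0.28, Plk1 at 0.99 ± 0.30 and the checkpoint kinase Bub1 at 0.97 ± 0.27 (SE, n = 2 each). The list's median was 0.46 and 0.91 for replicate numbers 1 and 2, 0.28 without wt replicate 2, and 0.33 (in the authors' values) to 0.68 over the scalings. Cholesterol and fatty acid synthesis genes were higher, with a median of 0.36 (0.21 and 0.53 by replicate number) and 23 of 26 higher, led by the desaturase Scd at 1.20 ± 0.47, with Stard4 at 0.54 ± 0.36, Dhcr7 at 0.51 ± 0.24 and Scd2 at 0.49 ± 0.23. NF-kappaB and immediate early genes were lower, with a median of −0.30 (−0.06 and −0.41) and 25 of 28 lower, such as Spry4 at −0.51 ± 0.37 and Nfkbia, the inhibitor of NF-kappaB, at −0.40 ± 0.27. Nr4a1 went against the list at 0.34 ± 0.24. In the authors' values Aspm, Nusap1, Plk1 and Bub1 lay at 0.61, 0.50, 0.47 and 0.40, Scd and Stard4 at 0.76 and 0.25, and Spry4 and Nr4a1 at −0.11 and 0.07. Camera gave adjusted p values of 1.01e-24, 3.81e-05 and 0.0118 in that order. Adjusted over the list alone, 0 genes of each passed in limma without the block, with 10, 1 and 0 at an unadjusted p under 0.05, and 15 cell cycle genes were higher with the block.

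The cholesterol call between the treatments was lost without kd replicate 2 (adjusted p = 0.735, median 0.09), and its median was 0.68 without kd replicate 1. The NF-kappaB call was lost without wt replicate 2 (0.53, median −0.16), kd replicate 1 (0.052, median −0.17) or kd replicate 2 (0.377, median −0.14), and with no filter (0.122). Its median was −0.19 without background correction and −0.16 in the authors' values. Without wt replicate 1, 6 lists passed and not 3, with detection on all arrays 5 passed, and with the replicate block 5 passed. The block added lower epithelial carcinoma markers (median −0.41; adjusted p = 0.0222 against 0.758) and lower interferon and antigen presentation genes (median −0.14; adjusted p = 0.0222 against 0.125), with the class I gene RT1-A1 at −0.33 ± 0.15 (SE with the block), and both lists had adjusted p = 0.746 with an estimated correlation. The block also gave 1 angiogenesis gene lower adjusted over the list alone, against 0 without it. Among single genes, the complement component C6 lay at −1.71 ± 0.35 and was detected in both groups, while Tec was not detected after kd exosomes (at least 1.89-fold lower, adjusted p of 1). C6 and Tec lay at −0.52 and −0.295 in the authors' values, against −1.24 for Tec here. Limma called 0 probes, and 230 had an unadjusted p under 0.05 (150 higher, 80 lower) where chance gives 582. That count was 393 with the replicate block (222 higher, 171 lower; 0 called, lowest adjusted p = 0.999), 418 without wt replicate 1 and 396 without kd replicate 1. It was 588 with no filter, 70 with detection on all arrays and 92 with all 12 arrays in 1 fit. The groups did not overlap for 20.6% of probes, where chance gives 33.3% for arrays that are not paired, unlike these. In the fit without the block, the 582 likewise holds only for arrays that are not paired.

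**Figure D4:**
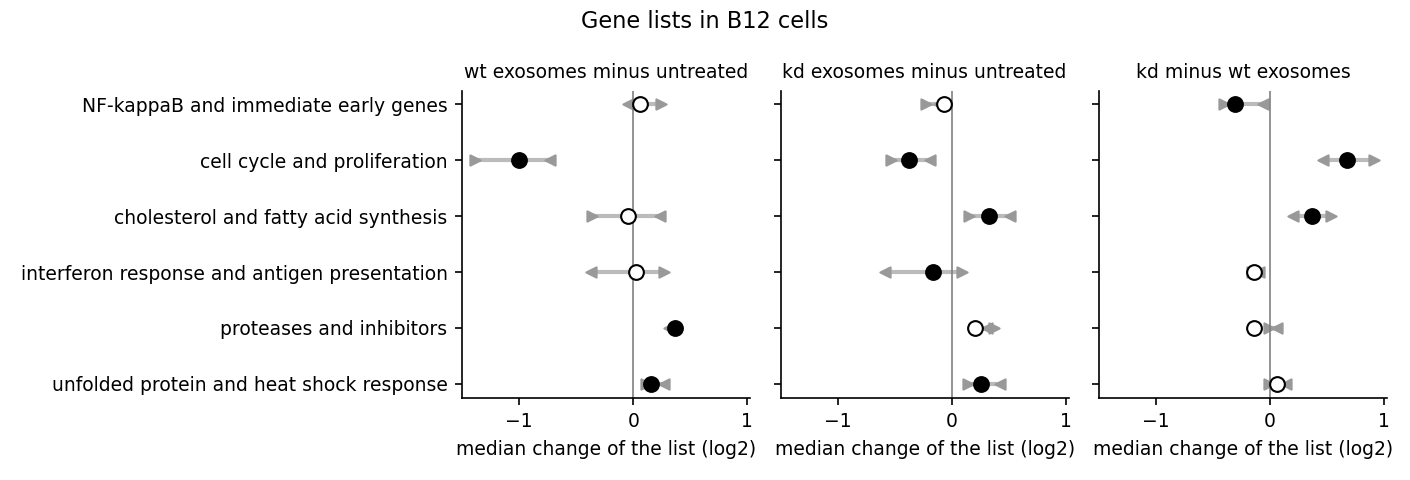
Median change in log2 of 6 gene lists in B12 cells for 3 comparisons; circles are medians over both replicates, filled where camera gave an adjusted p under 0.05 (0 lists with an estimated correlation), and grey triangles are the medians of replicate numbers 1 and 2. The cell cycle list fell by 1.00 with wt exosomes and fell by 0.37 with kd exosomes against untreated cells, and lies at 0.67 between them.

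Cd44 and Tspan8, both of which ASML exosomes carry, differed more between replicate numbers than between treatments in B12 cells. Cd44 averaged 10.32 ± 0.92 in untreated cells, 9.68 ± 0.89 with wt and 9.96 ± 1.16 with kd exosomes (log2, SD, n = 2 each). Its change was −0.65 ± 0.79 (SE) with wt exosomes, −0.36 ± 0.79 with kd exosomes and 0.28 ± 0.79 between them. Within replicate numbers 1 and 2 it was −0.62 and −0.67 with wt exosomes, −0.54 and −0.19 with kd exosomes, and 0.09 and 0.48 between them, with an SE of 0.18 with the block (adjusted p = 0.780, 0.858 and 0.999). Leaving out 1 array breaks such a pair, and the change then turned to 0.01 with wt and 0.29 with kd exosomes without untreated replicate 2, to 0.46 with kd exosomes without kd replicate 1, and to −0.34 and −0.54 between the treatments without wt replicate 1 or kd replicate 2. Tspan8 averaged 12.72 ± 2.81, 13.27 ± 1.47 and 12.09 ± 2.84 in the same groups. Its change was 0.55 ± 1.88 with wt exosomes (−1.43 without untreated replicate 2, −0.48 without wt replicate 1), −0.63 ± 1.88 with kd exosomes (1.35 without untreated replicate 1, 1.37 without kd replicate 2) and −1.18 ± 1.88 between them (0.83 without kd replicate 2). Within the numbers it went opposite ways with wt exosomes and was −0.61 and −0.65 with kd exosomes and −0.21 and −2.15 between them, with an SE of 0.47 with the block (adjusted p = 0.913, 0.882 and 0.999). Limma passed neither gene in any of these comparisons, with or without the block.

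The transcripts most abundant in exosomes relative to B12 cells were followed in the treated cells, to ask whether exosomal RNA was delivered in amounts the arrays can see. The 200 genes marking wt exosomes had a median change of −0.0057 after wt exosomes, with 94 higher and 106 lower (camera p = 0.859, n = 200 genes; percentile 46.8 of random lists, most of which lay between −0.0585 and 0.038). Their median change was −0.014 and 0.00814 for replicate numbers 1 and 2. The 200 marking kd exosomes had a median of −0.0434 after kd exosomes, with 92 higher and 108 lower (camera p = 0.296, n = 200 genes; percentile 6.3). Without untreated replicate 1 the medians turned to 0.0623 and 0.0202. The wt median was −0.032 under median scaling, and the kd median was −0.0045 in the authors' values. Of the genes marking wt exosomes, 59 were detected on no B12 array, 3 were detected on all treated and no untreated arrays, and 2 the other way; for kd exosomes these counts were 45, 2 and 4. No delivery was detectable by these measures. Low ranks in B12 cells treated with the other exosomes entered the choice, so genes delivered by both exosome types were chosen less often.

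The genes that differed most between kd and wt exosomes were followed in the same way. As under 20 genes were called, the 100 with the smallest p in each direction were taken. Of the 100 higher in kd exosomes, 90 were measured in B12 cells, with a median of 0.0047 between kd-treated and wt-treated cells (camera p = 0.616, n = 90 genes); it turned to −0.0027 and −0.0033 without untreated replicates 1 and 2 and to −0.037 without wt replicate 2, and also to −0.014 under cyclic loess and −0.0096 with rows without an identifier as controls. Of the 100 lower, 91 were measured, with a median of −0.0401 (camera p = 0.18, n = 91 genes).

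The changes after wt and after kd exosomes correlated at r = 0.624 across 11631 probes, which are not independent replicates, with a covariance of 0.0818. Both comparisons use the same 2 untreated arrays. In 100 simulations of unchanged groups these arrays alone gave r = 0.50 and a covariance of 0.163, so the observed covariance differed from it by −0.0808; with the replicate block the simulated covariance was 0.0378 and the difference 0.0441. At an unadjusted p under 0.05, 35 probes were higher and 50 lower after both, where independent lists give 1.49 and 2.53 and the simulations 77.3 and 78.1. With the block the counts were 107 and 102, against 7.65 and 11 for independent lists and 68.9 and 69.6 simulated. The controls cannot be split with 2 arrays, so part of the excess seen with the block may come from the shared controls. Without the block there was none in covariance or overlap. The spread simulated there includes the difference between replicate numbers, which cancels in the real comparisons, so this absence tells nothing. The correlation was 0.234 without wt replicate 2 and 0.199 without kd replicate 1.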

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

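The direct test between the treatments was planned, and of the tests on the cell cycle genes the one on a level shared by all treated cells was chosen only after the result was seen. The 3 gene lists below stood out because they differed between B12 cells treated with kd and with wt exosomes: cell cycle genes were higher with kd exosomes (median 0.67), cholesterol and fatty acid synthesis genes were higher (0.36), and NF-kappaB and immediate early genes were lower (−0.30). None of them passed with an estimated correlation, where each had an adjusted p of 0.641, and the last 2 were lost when single arrays were left out.

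The lower cell cycle genes after wt exosomes were weighed against 3 other explanations. A change confined to 1 replicate number would leave the other without it, but the weaker of the 2 medians was still −0.73. A difference between the numbers cancels here, as each group holds 1 array of each. Each median sets 1 array against 1, and the list's genes vary together. Differences between single cultures therefore cannot be judged. An effect of array signal or normalization would bring the list near 0 under another scaling, but the value nearest to 0 was −0.52. A low cell cycle level in treated cells of any exosomes cannot be judged, as the lower of the 2 medians between kd and wt treatment, 0.46, only restates the difference given above. The list did not pass with an estimated correlation (adjusted p = 0.752), and in replicate number 1 epithelial markers lay at −0.61 and stroma markers at 0.76 (0.21 and −0.36 in number 2), so an effect of wt exosomes on proliferation, a changed mix of cells, cell density and time of harvest all stay open, untested.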

How the results depend on the processing

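The cell cycle list kept its direction in every B12 comparison under all alternatives, and Cd44 stayed lower in kd exosomes under all of them. Over the alternatives, 79 counts of called probes stayed and 4 moved, 64 counts of lists stayed and 20 moved, and single lists kept their call in 180 cases, weakened in 49 and reversed in 2. The cause was not tested for any change below, except that leaving out an array leaves fewer samples.

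Between kd and wt exosomes the number of called probes was 1 with all 12 arrays in 1 fit, 4146 with array weights and 0 to 4304 with arrays left out; the calls of kd replicates 1 and 2 became 0 with kd replicate 3. Lists past the threshold were 0 with fry and 0 with an estimated correlation in all 4 comparisons. Between kd and wt exosomes they were 3 under median scaling, 3 with detection on all arrays, 2 under cyclic loess and 1 to 5 with arrays left out. They were 2 to 6 with wt exosomes, 2 to 6 with kd exosomes (7 with the block) and 2 to 6 between the treatments (5 with the block, 5 with detection on all arrays) with B12 arrays left out. Cd44 in exosomes was −1.15 with array weights (adjusted p = 8.75e-04) and −1.46 to −1.19 with arrays left out. The weights come from the same values, so that p does not hold as a test of the knockdown.

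Under median scaling the epithelial list turned to 0.066, Krt7 to 0.014 and Spint2 to 0.11 between kd and wt exosomes, and Tspan8, Vim and Fdps to 0.14, 0.12 and 0.20 for kd replicates 1 and 2, all below the median of all probes under that scaling. With arrays left out, the cholesterol list after kd exosomes ranged from −0.023 to 0.69. The genes marking exosomes ranged from −0.032 to 0.062 with wt and −0.061 to 0.020 with kd exosomes. The genes higher in kd exosomes ranged from −0.037 to 0.071 between the treatments (−0.0096 with rows without an identifier as controls, −0.014 under cyclic loess). The similarity of the treatments ranged from 0.199 to 0.909. In B12 cells, the lowest and highest values with arrays left out were for Cd44 −1.30 and 0.0091 with wt exosomes, −1.19 and 0.46 with kd exosomes and −0.54 and 1.11 between the treatments, and for Tspan8 −1.43 and 2.53 with wt exosomes, −2.63 and 1.37 with kd exosomes and −3.18 and 0.83 between the treatments.

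The replicate block changed no other call in the B12 cells. In the exosomes, arrays with the same number did not resemble each other throughout (−0.198, 0.456 and 0.325), kd replicate 1 correlated best with wt replicate 2 (0.446), and the block gave 0 calls and 1 list. A block by chip was not run, as all arrays shared 1 chip. The low signal of the exosome arrays, 100.1 to 299 over background on average, limits small changes in faint transcripts.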

Other observations

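Of the tests in this part, those on kd exosome replicate 3 and those on detection were chosen only after the result was seen. Exosomes and B12 cells each had transcripts the other lacked. Of 21946 probes, 70 were detected on all exosome and no B12 arrays, 488 on all B12 and no exosome arrays, 6304 on all 12 and 5595 on none. Epcam, the epithelial adhesion molecule, averaged 948 over background in exosomes and −13 in B12 cells, and Cldn3, a tight junction gene, 356 in exosomes. Lgals4 and Cdh17, both intestinal epithelial genes, were detected on all B12 arrays and on no exosome array, with Cdh17 at 2548 over background in untreated replicate 1 and 58.1 to 789.5 on the other B12 arrays. Tspan8 lay at 299.9 to 683.6 on the exosome arrays and at 1094 to 24797 on the B12 arrays. Krt19 lay at 5738 to 13121 on the exosome arrays, at 14920 in untreated B12 replicate 1 and at 719.8 to 5500 on the other B12 arrays.

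B12 arrays numbered 1 and 2 differed more than any treatment. The 3 arrays of a number are the untreated, wt-treated and kd-treated arrays, not replicates of that number. SEs, p values and calls here therefore rest on the spread left between arrays after group and number, not on a spread between cultures. Number 1 had more of the intestinal lectin Lgals4 (3.91 ± 0.30, log2, SE, 3 arrays each), Gsta5 (6.10), Anxa3 (5.85), Tspan8 (3.35 ± 0.38) and Krt8 (2.45). It had less of the stromal chemokine Cxcl12 (−6.88 ± 0.14), Pdgfra (−6.78), the matrix genes Lum (−5.91), Dcn (−4.41) and Col1a2 (−3.16), Vcam1 (−5.16) and Cd44 (−1.40 ± 0.15; limma adjusted p = 0.00238). Limma called 2284 of 11630 probes, 1191 higher and 1093 lower in number 1. Epithelial carcinoma markers were higher (median 2.09; adjusted p = 1.77e-05, and adjusted p = 0.865 with an estimated correlation), and stroma and fibroblast markers were lower (−1.25; adjusted p = 4.17e-06, and adjusted p = 0.865 with an estimated correlation). ASML cells or their exosomes in the cultures would raise 200 genes that rank higher in exosomes than over the B12 arrays. In number 1, 123 of them were higher, with a median difference of 0.064 (quartiles −0.14 and 0.47). As low ranks on these same B12 arrays entered the choice, genes raised in number 1 were chosen less often. The median therefore cannot limit the share of such material. Such material is not the whole cause, as Epcam, abundant in the exosomes, was not detected on B12 arrays of number 1, and Lgals4 was not detected in the exosomes. Epcam lay at −9.9, −11.8 and −13.3 over background there, and Cldn3 was detected on no B12 array. Rab25 and Pkp3 averaged 755 and 794 in exosomes and 24.3 and 29.3 on B12 arrays. These genes argue against a large share of such material, while Krt8 and Krt19, bright in both, cannot tell. A small share stays open. Normalization does not account for the difference either, as at least 95.8% of the calls were also called under cyclic loess or in the authors' values.

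Kd exosome replicate 3 lay with the wt exosome arrays. A low signal of the array would leave its 6196 bright probes with the other kd arrays, but on a scale from 0 at the wt mean to 1 at the mean of kd replicates 1 and 2 these probes lay at −0.087. A mislabelled wt sample would carry wt levels of Cd44, but Cd44 lay at −6.76 SDs of the 3 wt arrays from their mean. Its signal was only 17.3 over background, where the SD of rows without an identifier was 10.4. Cd44 therefore cannot exclude a mislabelled sample, which stays possible. Of 86 probes detected on all wt arrays and not on kd replicates 1 and 2, 73 were detected on kd replicate 3. Of 407 the other way, 33 were, a count that a dim array lowers as well. These counts show RNA like that of wt exosomes, but cannot tell a mislabelled sample from a kd preparation with such RNA. Splits of the 6 exosome arrays into 3 and 3 are too few for a share under 0.05: the real one called 0 probes, which all 10 of 10 splits meet, so that count tells nothing, with 106 as the highest other, and 6 of 10 gave as many lists as its 1, with 4 as the highest other. The split with 106 calls set wt replicates 1 and 3 with kd replicate 3, which points to a structure of the samples other than the labels.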
